A study of Mus musculus with 10 samples.

How the data were processed

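Gene expression was measured in whole mouse lenses, wild type (WT) or with a conditional null allele of Klf4 (labelled Klf4CN). Embryonic lenses were from day 16.5 of gestation (E16.5) and adult ones from postnatal day 56 (PN56). Per the labels' protocols, each E16.5 sample was an independent preparation of lenses pooled from 5 embryos and each PN56 sample one of lenses pooled from 3 young adults. Total RNA was isolated with an RNeasy kit, amplified and biotin-labelled with a 3' IVT Express kit and hybridised to Affymetrix mouse 430 2 arrays, 1 array per sample, per the labels. There were 3 arrays per genotype at E16.5 and 2 per genotype at PN56, 10 in all, and their number limits the precision of each comparison.

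The deposited values were linear intensities, 1 signal per probe set and array. Per the submitters' processing notes they were made with GCOS 1.4; other steps are not given in the sources used here. On each of the 10 arrays the mean signal after trimming 2% at each end came to 500, so the deposited values had been scaled array by array to a common level. No detection call was used here. Of 45101 probe sets, 64 were controls, 34958 carried a single gene symbol, 932 several and 9211 none; 34754 symbols were matched through their gene number to RefSeq names of assembly GRCm38.p6, and 0 changed. The named probe sets stood for 18194 genes.

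Signals were tested as log2(signal + 16) with no further scaling, so that a fold change understates the change of dim genes. The brightest probe set of a gene, by its mean over the 10 arrays, stood for it. A gene was tested when that mean was at or above the 40th percentile of all probe sets, a signal of about 45, which left 13450 genes. All 10 arrays entered one limma fit (version 3.58.1 in R 4.3.3) with 4 group means, because 2 arrays per group give little measure of spread by themselves; eBayes was run with an intensity trend, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. All limma tests were two-sided. Comparisons were Klf4CN against WT at each age, the difference between those effects, and PN56 against E16.5 within each genotype. Adjusted p-values given for genes are from this fit.

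The 32 gene lists were fixed before the data were examined: crystallins, lens fibre genes, lens epithelium genes, lens transcription factors, Kruppel-like factors, lists of processes and signalling pathways, and markers of tissues a dissected lens could carry along. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with an estimated correlation, and with fry, adjusted over the 32 lists. Named genes followed a rule fixed before the data were examined: Klf4 first; in each comparison the 10 largest rises and 10 largest falls among called genes whose groups did not overlap, filled up with genes of smallest p, given as not past the test, where fewer than 10 passed; up to 4 members of smallest p from each list; and for the difference between ages up to 10 genes of smallest p.

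The fit was tested on simulated data of 13450 genes with known changes. Noise was drawn independently for each gene from the fit's own SDs, with no array effects and no correlation between genes. The shares below therefore need not hold for the real arrays. For Klf4CN against WT at E16.5, 22.4% of genes changed 1.5-fold, 56.7% of those changed 2-fold and 89.4% of those changed 4-fold were recovered, with 11 false calls among 123. For the same comparison at PN56 the shares were 16.4%, 41.8% and 83.3%, with 3 false calls among 97.

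Alternatives were quantile normalization, centring each array on its median, offsets of 1 and 64, no filter, a filter at the 60th percentile, every probe set by itself, the mean of a gene's probe sets, no intensity trend, array weights, a fit on the 2 compared groups, leaving out each array in turn (where 1 array of a PN56 group remains, it is assumed to vary like the other groups), the replicate number as a block, and other thresholds. Age was tied to the number of animals pooled. Poly-A spike controls were near background on all PN56 arrays and present on all E16.5 arrays (dap, 6098 ± 1077 on WT and 5970 ± 435 on Klf4CN arrays at E16.5, SD, n = 3; 7.6 and 50.05 on average at PN56), so age cannot be told apart from preparation.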

Results

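The data comprised 10 arrays of whole mouse lens. At E16.5, a stage of fibre cell formation, 3 arrays were labelled WT and 3 Klf4CN. At PN56, in young adults, 2 arrays were labelled WT and 2 Klf4CN. Median signals ran from 63.0 to 76.9 at E16.5 and from 91.0 to 108.6 at PN56, after the deposited scaling of each array to a trimmed mean of 500. Pearson correlations of log2 signals between arrays of a group, taken across the 13450 tested genes, lay between 0.952 and 0.9811. The first principal component held 69.9% of the variance and parted the ages, and the second held 8.3% and parted the genotypes at PN56.

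The targeted gene was examined first. Klf4, a zinc finger transcription factor, had a signal of 739 ± 295 in WT and 1079 ± 278 in lenses labelled Klf4CN at E16.5 (SD, n = 3 each). At PN56 the signals were 185 ± 40.3 in WT and 717 ± 20.9 in lenses labelled Klf4CN (SD, n = 2 each). The log2 difference was 0.59 at E16.5 (limma adjusted p = 0.9998) and 1.88 at PN56 (limma adjusted p = 0.0041), so that Klf4 signal was higher, not lower, in the lenses labelled Klf4CN at PN56. A second probe set gave 0.65 at E16.5 and 1.04 at PN56, the latter not past the test (limma adjusted p = 0.077). The labels do not say whether either probe set lies in the deleted part of the gene, and a probe set outside it checks nothing. Every direction below is therefore that of the lenses labelled Klf4CN.

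**Figure D1:**
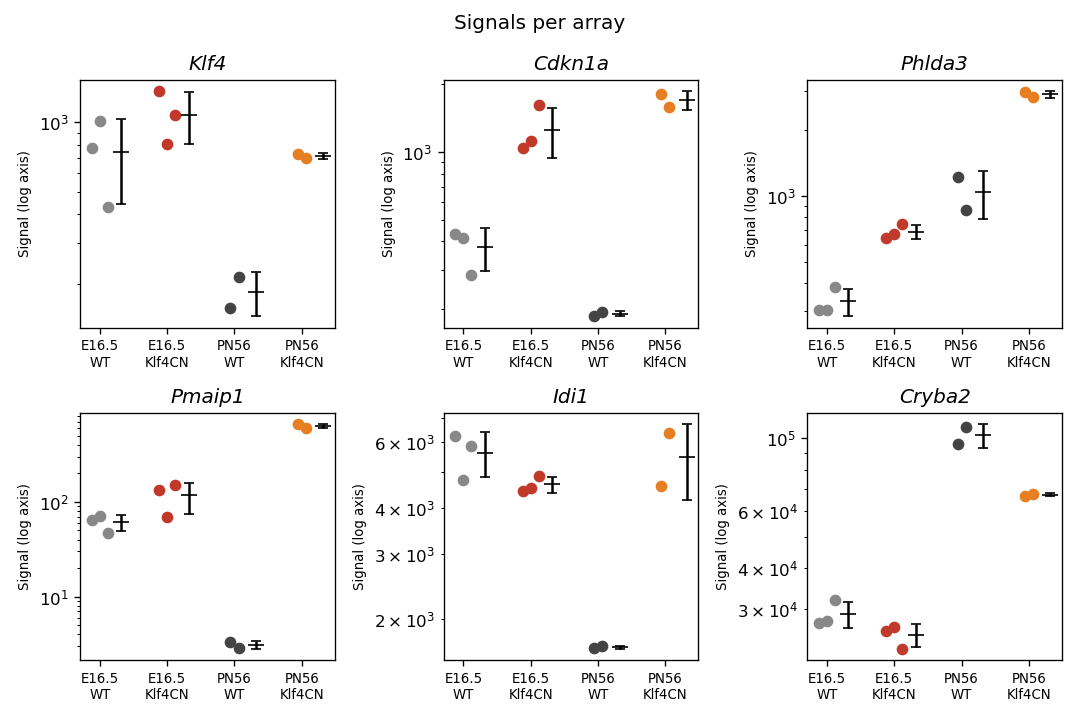
Signals of 6 genes on each of the 10 arrays (points; vertical log axis, arbitrary intensity units), by age and labelled genotype, with group mean and SD beside them. Cdkn1a lay near 1256 on average in E16.5 lenses labelled Klf4CN against 378 in WT.

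The comparison at E16.5 asked what conditional loss of Klf4 changes in the embryonic lens. Cdkn1a, which encodes the cyclin-dependent kinase inhibitor p21, rose from 378 ± 81.5 in WT to 1256 ± 312 in lenses labelled Klf4CN (SD, n = 3 each), a log2 change of 1.69 ± 0.20 (SE; limma adjusted p = 0.021). It was the only one of 13450 genes called. On the same arrays the control probe set for the 5' part of 18S ribosomal RNA had a signal of 1869 ± 646 in WT and 21780 ± 945 in lenses labelled Klf4CN (SD, n = 3 each), and the cre hybridisation spike 43390 ± 4626 and 38580 ± 1276. Genes of next smallest p were not past the test. Among them Phlda3, a p53 target, was at log2 1.03 (adjusted p = 0.059), Eda2r, another p53 target, at 2.00 (0.069) and Acta2, smooth muscle actin, at 0.66 (0.080). Values for Hspb1, Trp53inp1, Ephx1, Hmox1, Me1 and Serpinb6b ran from 0.48 to 0.87. On the lower side, also not past the test, were Gstm1, a glutathione transferase, at -0.58 (0.055), Tppp3 at -0.60 (0.055) and Rcan2 at -0.67 (0.059). Values for Antxr1, Emilin3, Cdh1, Niban2, Fzd1 and Plekhg1 lay between -0.69 and -0.44, and Prm1 was at -1.58. Second probe sets of Antxr1 and Plekhg1 had the opposite sign.

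At E16.5, 14 of the 32 lists passed camera with the preset correlation, 0 with an estimated correlation and 0 by fry. All 9 pigment cell markers were on the higher side, with a median log2 difference of 1.34 and 0 of 9 past the test over all genes (5 adjusted over the list alone; camera adjusted p = 2.728e-10, adjusted p = 0.236 with an estimated correlation). Pmel was at 1.92, Tyrp1 at 1.85, Dct at 2.09 and Mlana at 1.98. The pigment median was 0.86 without Klf4CN replicate 2, Dct was at 2.89 and Mlana at 2.57 without Klf4CN replicate 3, and Mlana at 2.71 without WT replicate 3. The 13 markers of retinal progenitors and neurons had a median of 1.65, with 0 past the test (camera adjusted p = 1.949e-09, adjusted p = 0.327 with an estimated correlation), among them Nefm at 1.65. Without WT replicate 1 their median was 0.63 and Nefm was at 0.86, and without WT replicate 2 the median was 2.02. The mean log2 signal of both marker lists together was 6.31 on WT replicate 1, 8.24 and 8.30 on the other WT arrays, and 8.57, 9.73 and 8.81 on the arrays labelled Klf4CN. Of 19 genes of cell cycle exit and p53, 1 rose and 18 did not pass (3 higher adjusted over the list alone), with a median of 0.12 (camera adjusted p = 0.0022, adjusted p = 0.236 with an estimated correlation); Ccng1 was at 0.65. That median was 0.18 without WT replicate 1 or Klf4CN replicate 2, 0.06 without WT replicate 2 and 0.05 without Klf4CN replicate 3. Crystallins, the structural proteins of the lens, had a median of -0.21 (-0.14 without WT replicate 3) with 0 of 14 past the test (adjusted p = 0.327 with an estimated correlation).

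The remaining lists past camera at E16.5 held 0 called genes each. Cell cycle, heat shock, FGF signalling, macrophages and mesenchyme were on the higher side, with medians from 0.12 to 0.34, and sterol synthesis, lens epithelium genes, glycolysis, lens fibre genes and hypoxia response on the lower side, with medians from -0.15 to -0.10. Over arrays left out the medians of the first 5 lay between 0.06 (cell cycle, without Klf4CN replicate 2) and 0.62 (mesenchyme, without Klf4CN replicate 1), and those of the others between -0.21 (sterol synthesis, without WT replicate 2) and -0.04 (lens fibre genes and hypoxia response, without Klf4CN replicate 2). Without WT replicate 1 mesenchyme and hypoxia response were not past camera, without WT replicate 2 these, FGF signalling and lens epithelium genes, and without WT replicate 3 macrophages, sterol synthesis and lens fibre genes. Without Klf4CN replicate 1 macrophages and mesenchyme were not, without Klf4CN replicate 2 cell cycle, mesenchyme, lens fibre genes and hypoxia response, and without Klf4CN replicate 3 macrophages, FGF signalling, lens epithelium genes and hypoxia response. Hypoxia response was not past it without either PN56 WT array, nor mesenchyme without PN56 Klf4CN replicate 2, and each of these 2 lists lost its call in 12 of 22 alternatives, hypoxia response turning direction in 1 more. Calls also ended with quantile normalization for lens fibre genes (camera adjusted p = 0.982, median -0.02), with a gene's probe sets averaged for lens epithelium genes (0.141). They ended for heat shock (0.060), cell cycle (0.436) and lens fibre genes (0.295) with the mean of the pigment and retinal markers as a covariate. That covariate was chosen after the data were seen. With an estimated correlation the adjusted p was 0.142 for heat shock, 0.401 for hypoxia response, 0.383 for lens fibre genes, 0.566 for macrophages and 0.327 for the others. Across genes, 606 had an unadjusted p under 0.05 where 672 would be expected by chance, and the groups did not overlap for 11.8% of genes, against 10% by chance. The call of Cdkn1a was lost in 16 of the 25 alternatives in which it was followed, with adjusted p from 0.0087 to 0.507 over them, and also with a fit on the 2 compared groups, which called 0 genes. With array weights Phlda3, Eda2r, Acta2, Trp53inp1, Gstm1, Tppp3 and Rcan2 were past the test too. So were Gstm1 and Tppp3 with quantile normalization, and Phlda3, Gstm1 and Rcan2 with the replicate number as a block (limma adjusted p = 0.0498 for each). Without E16.5 Klf4CN replicate 1 Rcan2 was past it and without its replicate 2 Hspb1. The count was 0 without any 1 of E16.5 WT replicates 1 or 2, E16.5 Klf4CN replicate 3 or any PN56 array, 3 without E16.5 WT replicate 3, and 2 without E16.5 Klf4CN replicate 1 or replicate 2.

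The comparison at PN56 asked the same of the adult lens. In lenses labelled Klf4CN 812 genes rose and 938 fell, 1750 of 13450. Pmaip1, which encodes the pro-apoptotic protein Noxa, rose from a signal of 3.1 in WT, below the offset of 16, to 632 (limma adjusted p = 2.444e-05). The size of its log2 change, 5.08, was set by the offset, being 3.37 with an offset of 64 and 7.27 with an offset of 1. The lipoxygenase genes Alox12 and Alox15 rose by 3.96 and 3.69. Pdlim2 rose by 4.05, Rgs13 by 3.83, Ptgfr, the prostaglandin F receptor, by 3.78, Ddn by 3.57, Rftn2 by 3.44, Cabp5 by 3.34 and Lypd6b by 3.32. Large falls were those of Lrrc66 (-2.83), Magel2 (-2.78), Zfp526 (-2.75), Doc2b (-2.74), Prokr1 (-2.68), Dmbx1 (-2.56), Fmo2 (-2.55), Hebp1 (-2.55), 4930413G21Rik (-2.53) and Clrn1 (-2.52). Without PN56 Klf4CN replicate 2, Ddn was at 1.74 and Fmo2 at -0.83, neither past the test; without replicate 1 of that group they were at 5.39 and -4.26, and without either PN56 WT array neither was past the test. The call of Fmo2 was lost in 13 of the 18 alternatives in which single genes were followed, among them each of the 6 E16.5 arrays left out. Ptgfr was at 4.49 and 3.06 without PN56 WT replicates 1 and 2, and Doc2b at -1.99 and -3.48 without PN56 Klf4CN replicates 1 and 2. Signals of Rgs13 (13.7) and Ddn (14.4) in WT and of Magel2 (7.2), Zfp526 (9.45) and 4930413G21Rik (10.3) in lenses labelled Klf4CN also lay below the offset, so that the sizes and order of their changes depend on it. The genotypes at PN56 differed in control signals too, without overlap: the Actb 3' to 5' ratio was 1.84 ± 0.07 in WT and 1.53 ± 0.10 in lenses labelled Klf4CN, the cre hybridisation spike 110200 ± 10350 and 73060 ± 2601, and the 5' part of 18S ribosomal RNA 1699 ± 1656 and 8353 ± 3751 (SD, n = 2 each). The Gapdh 3' to 5' ratio was 0.719 ± 0.013 and 0.71 ± 0.042.

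Genes of cholesterol synthesis rose together at PN56: 10 of 17 rose, 1 fell and 6 did not pass (the same adjusted over the list alone), with a median of 0.60 (camera adjusted p = 4.494e-06, adjusted p = 0.254 with an estimated correlation). Idi1 rose by 1.68, Sqle, squalene epoxidase, by 1.06, Cyp51 by 0.68 and Fdft1 by 0.60. Of 19 genes of cell cycle exit and p53, 6 rose, 1 fell and 12 did not pass (8 and 2 adjusted over the list alone; camera adjusted p = 0.0014, adjusted p = 0.254 with an estimated correlation). Cdkn1a rose by 3.05 ± 0.24 (SE; limma adjusted p = 2.069e-05), from 191 ± 5.16 to 1701 ± 163 (SD, n = 2 each), and Phlda3 by 1.49, while Cdkn1c, encoding the inhibitor p57, fell, at -0.69. Of 20 antioxidant genes 4 rose and 1 fell (5 and 1 adjusted over the list alone; camera adjusted p = 0.019, adjusted p = 0.254 with an estimated correlation): the glutathione peroxidases Gpx1 and Gpx4 rose by 1.22 and 0.91, Gstp1 by 0.72, and catalase, Cat, fell, at -0.65. Of 19 autophagy and lysosome genes 5 rose and 1 fell (the same adjusted over the list alone; camera adjusted p = 0.019, adjusted p = 0.668 with an estimated correlation), with Sqstm1 at 1.39, Map1lc3b at 0.89, Ctsb at 0.60 and Map1lc3a at 0.57; a second probe set of Map1lc3b had the opposite sign. With quantile normalization or with a gene's probe sets averaged, neither of the last 2 lists was past camera. The antioxidant list was not past it with every probe set by itself (adjusted p = 0.208), and the autophagy and lysosome list was not past it without PN56 WT replicate 2 (median 0.04) or PN56 Klf4CN replicate 1 (0.08).

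Crystallins were lower at PN56: 10 of 14 fell and 0 rose (11 and 0 adjusted over the list alone), with a median of -0.46 (camera adjusted p = 1.621e-05, adjusted p = 0.668 with an estimated correlation). The log2 change was -1.03 for Crygf, -0.60 for Cryba2, -0.60 for Cryaa and -0.48 for Cryba4. With quantile normalization the median was -0.10, the list was not past the test (camera adjusted p = 0.191), and the calls of Cryba2, Cryaa and Cryba4 were lost. That scaling gives all arrays the same distribution, so it removes a joint change of the brightest signals whatever its source. Bright control signals were lower in lenses labelled Klf4CN too, without overlap. The cre hybridisation spike averaged 110200 on WT arrays and 73060 on arrays labelled Klf4CN. Actb 3' averaged 81660 and 62490, and Gapdh 3' 55500 and 48060. The B1 repeat and the 5' part of 18S ribosomal RNA were higher. A fall of crystallins therefore cannot be told apart from one of bright signals in general. Of 16 lens fibre genes 7 fell and 2 rose (the same adjusted over the list alone), and the list was not past the test (camera adjusted p = 0.058, past it in 4 of 21 alternatives, at 0.037 without PN56 Klf4CN replicate 2). Dnase2b, the nuclease of fibre denucleation, was at -1.38, Bfsp1, a beaded filament protein, at -0.73 and Tdrd7 at -0.68, and Gje1, a connexin gene, rose by 2.03. Of 15 lens epithelium genes 5 fell and 0 rose, the list not past the test (camera adjusted p = 0.053, past it in 8 of 21 alternatives with 0.027 as the lowest), with Gja1 at -1.26, Foxe3 at -1.03, Aqp1 at -1.001 and Tfap2a at -0.52. Of 18 genes of lens capsule and basement membrane 3 fell (camera adjusted p = 0.053, not past the test, but past it in 5 of 21 alternatives), namely Col4a1 at -0.90, Col4a5 at -0.68 and Nid1 at -0.38.

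**Figure D2:**
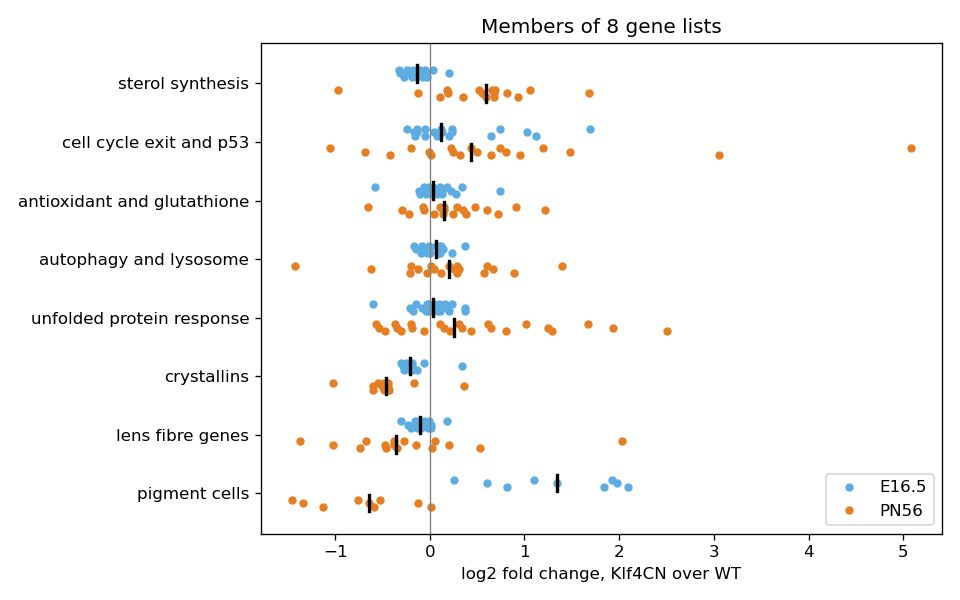
Log2 fold change (horizontal axis) of each measured member of 8 gene lists in lenses labelled Klf4CN against WT, at E16.5 and at PN56; black bars are list medians. The median of sterol synthesis was -0.14 at E16.5 and 0.60 at PN56, and that of pigment cells 1.34 and -0.65.

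Of 24 genes of the unfolded protein response 7 rose and 3 fell, among them Asns at 1.94, Sdf2l1 at 1.67, Atf4 at 1.25 and Canx at 0.62; the list passed fry (adjusted p = 0.0014) and not camera (adjusted p = 0.053, and adjusted p = 0.254 with an estimated correlation), and was past the test in 7 of 21 alternatives. Asns was at 2.53 and 1.35 without PN56 WT replicates 1 and 2. Of 17 heat shock genes 4 rose, Hsph1 by 0.92, Hspe1 by 0.82, Hspa4l by 0.60 and Hspd1 by 0.38; the list passed fry (adjusted p = 0.038) and not camera (adjusted p = 0.191, and adjusted p = 0.668 with an estimated correlation). Cell cycle genes went both ways, with 3 higher and 4 lower of 33 (median 0.19, mean -0.011; camera adjusted p = 0.603): Ccnd2 rose by 1.01 and E2f1 by 1.49, and the replication genes Mcm2 and Mcm6 fell, at -1.74 and -1.56; a second probe set of E2f1 had the opposite sign. The cell cycle median was 0.03 and -0.07 without PN56 WT replicates 1 and 2, and -0.0025 and 0.05 without PN56 Klf4CN replicates 1 and 2. Of 17 macrophage markers 2 rose, Cd68 by 2.74 and Tyrobp, from a WT signal of 15.4, below the offset, by 2.42 (camera adjusted p = 0.053, not past the test, but past it in 5 of 21 alternatives). The list's median of 0.39 was 1.07 without PN56 Klf4CN replicate 2 (camera adjusted p = 3.437e-04) and -0.23 without replicate 1 of that group (camera adjusted p = 0.571), and Cd68 was at 2.03 and 3.46 without PN56 WT replicates 1 and 2. Of 18 genes of epithelial-mesenchymal transition and TGF-beta 2 rose, 3 fell and 13 did not pass (3 and 3 adjusted over the list alone; camera adjusted p = 0.727). The median was -0.16 (-0.27 and 0.05 without PN56 Klf4CN replicates 1 and 2) and the mean 0.011. Tgfbi rose by 2.09 and Acta2 fell, at -0.65. Pigment cell markers had a median of -0.65 with 0 of 9 past the test (camera adjusted p = 0.191). Retinal progenitor and neuron markers had -0.09 with 0 of 13 (camera adjusted p = 0.727), and -0.46, -0.23 and -0.37 without PN56 WT replicate 1 and PN56 Klf4CN replicates 1 and 2. All 12 photoreceptor markers were on the higher side with 0 past the test (median 0.37, camera adjusted p = 0.211). The median was 0.24 without PN56 WT replicate 2, -0.31 without PN56 Klf4CN replicate 1 (camera adjusted p = 0.571), and 1.15 without replicate 2 of that group, where the list passed camera (adjusted p = 3.437e-04). Groups did not overlap for 50.8% of genes, against 33.3% by chance. With each array centred on its median 71.9% of calls were rises, against 46.4% as deposited; the count was 1079 without PN56 WT replicate 1 and 1058 without PN56 Klf4CN replicate 2. Beside those already given, calls among the genes named here were lost when 1 PN56 array was left out, at adjusted p between 0.052 and 0.217. Without WT replicate 1 they were those of Acta2, Cat, Doc2b, Gja1, Hspa4l, Hspd1, Hspe1, Lrrc66, Mcm6, Nid1 and Tfap2a. Without WT replicate 2 they were those of Clrn1, Col4a5, Cryaa, Cryba4, Doc2b, Foxe3, Gja1, Hspd1 and Nid1. Without Klf4CN replicate 1 they were those of Cat, Doc2b, Gja1, Hspd1 and Map1lc3a, and without Klf4CN replicate 2 those of Col4a5, Cryaa, Foxe3, Gja1, Hspa4l, Hspd1, Hspe1, Lrrc66, Nid1 and Tfap2a, while Mcm6 moved to -0.94 (-2.18 without Klf4CN replicate 1). The call of Tfap2a was lost in 10 of 18 alternatives, among them 4 of the 6 E16.5 arrays left out. With a gene's probe sets averaged the calls of 4930413G21Rik, Acta2, Col4a5, Ctsb, Cyp51, E2f1, Fdft1, Fmo2, Gja1, Map1lc3b, Mcm6, Nid1, Prokr1, Sqstm1, Tdrd7 and Tfap2a were lost. With each array centred on its median those of Acta2, Cat, Col4a5, Cryaa, Cryba4, Foxe3, Nid1 and Tfap2a were lost, and with quantile normalization that of Hspd1 beside the crystallins. Array weights and a fit with no intensity trend each ended those of Cat, Col4a5, Cryaa, Cryba4, Ddn, Fmo2, Foxe3, Gja1, Hspd1, Nid1 and Tfap2a. The weights also ended those of Clrn1, Doc2b, Hspa4l, Lrrc66 and Map1lc3a, and the fit with no trend that of Hspe1.

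The effects at the 2 ages were compared by a test of the difference. It was past the threshold for 644 genes, 362 with a higher and 282 with a lower effect at PN56. Gje1 differed by 2.03, Alox12 by 3.88, Cdk2ap2 by 2.51, Gpx1 by 1.33, Ppp1r14b by 1.42, Lypd6b by 3.46, Cabp5 by 3.09 and Pdlim2 by 3.91, and in the other direction Eva1a by -2.63 and Gprc5b by -1.77; a second probe set of Gprc5b had the opposite sign. Pmaip1 (4.34), Idi1 (1.95), Cdkn1a (1.36) and Acta2 (-1.31) were also past this test, that of Cdkn1a being lost in 11 of the 18 alternatives in which single genes were followed, with adjusted p from 0.016 to 0.340 over them. With a gene's probe sets averaged the calls of Acta2 and Ppp1r14b were lost as well (limma adjusted p = 0.111 and 0.148). The difference of Pmaip1 ran from 2.87 to 6.40 over the alternatives, its WT signal at PN56 of 3.1 lying below the offset of 16. The sterol synthesis list differed (camera adjusted p = 3.407e-08, adjusted p = 0.407 with an estimated correlation). Across genes, which are not independent replicates, the 2 sets of log2 fold changes had a Pearson's r of 0.056. Cdkn1a was the 1 gene called at both ages. Of the genes called at PN56, 43 were higher at both ages with an unadjusted p under 0.05 at E16.5, against 20.8 for independent lists (two-sided Fisher's exact test over genes, p = 5.461e-06), and 48 were lower at both, against 18.2 (p = 4.438e-10), while 26 had opposite directions. That threshold was chosen after the data were seen, and the Fisher test takes genes as independent, so its p-values do not measure repeatability over lenses. Both comparisons also share the fit's error estimate for each gene. Genes of small error can thus enter both lists more often than independent lists allow. Of all 1750 genes called at PN56, 969 (55.4%) had the same sign at E16.5. With each array centred on its median 470 genes were called and 83.2% of them were higher, against 56.2% as deposited, the median of all genes then lying at 0.11. The count was 323 without E16.5 WT replicate 1, 374 without its replicate 2, 329, 397 and 277 without E16.5 Klf4CN replicates 1, 2 and 3, 388 without PN56 WT replicate 1 and 386 without PN56 Klf4CN replicate 2.

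Between E16.5 and PN56 in WT, 3357 genes were higher and 4126 lower at PN56. Aldh3a1, a corneal crystallin and aldehyde dehydrogenase, rose by 9.03, Nfix by 6.53, Gnat1, rod transducin, by 6.12, Efemp1 by 6.08, Sbspon by 6.0003, Fmod by 5.87, Il33 by 5.87, Fam107a by 5.76, Tmem178 by 5.72 and Rgs4 by 5.68. Large falls, as log2 changes, were those of Capn3, a calpain protease (-8.50), Igf2 (-7.37), Rian (-6.51), Hbb-y, an embryonic globin (-6.50), Gask1b (-6.15), Cyyr1 (-6.10), Cd34 (-6.10), Alas2 (-6.04), Hbb-b2 (-5.77) and Fscn1 (-5.68). Igf2 was at -6.12 and -8.63 and Cyyr1 at -4.87 and -7.33 without PN56 WT replicates 1 and 2. Signals of Aldh3a1 and Gnat1 at E16.5 and of Hbb-y, Alas2 and Hbb-b2 at PN56 lay below the offset, as did those of Pde6b at E16.5 and Bub1 at PN56 among the genes that follow and of Scg2 at E16.5 in lenses labelled Klf4CN, so that the sizes and order of these changes depend on the offset. Of 33 cell cycle genes 31 fell (32 adjusted over the list alone), including Bub1 at -4.53 and Cdk1 at -3.37; a second probe set of Bub1 had the opposite sign. Of 14 crystallins 12 rose and 1 fell (13 and 1 adjusted over the list alone), including Crybb2 by 5.15, Crybb1 by 2.27 and Cryaa by 2.12. With quantile normalization the list's median went from 1.58 to 0.18, and the list was not past the test (camera adjusted p = 0.112). That scaling gives all arrays the same distribution, so it removes a joint change of the brightest signals and cannot decide on this rise. Blood vessel markers fell in 13 of 14, red blood cell markers in 6 of 6 and macrophage markers in 12 of 17. Photoreceptor markers rose in 10 of 12 (Pde6b by 4.60 and Sag by 4.34), pigment cell markers in 6 of 9 (Dct by 3.94) and heat shock genes in 10 of 17 (Hspb1 by 4.65), while Gje1 was at -4.66. These 8 lists passed camera and none passed with an estimated correlation, the adjusted p then lying between 0.349 and 0.667. Macrophages were not past camera with each array centred on its median (adjusted p = 0.05008), heat shock with a gene's probe sets averaged (0.152) and photoreceptors with a filter at the 60th percentile (0.052). In lenses labelled Klf4CN 2905 genes were higher and 4099 lower at PN56, with rises of Aldh3a1 by 8.15, Scg2 by 7.47, Tinag by 7.28 and Aqp5 by 5.96 and a fall of Capn3, at -8.09. Centring on the median moved the median of all genes from -0.04 to -0.56 in WT and the share of rises from 44.9% to 19.9%, and in lenses labelled Klf4CN from -0.10 to -0.45 and from 41.5% to 22.5%. Age is tied to the number of animals pooled and to the use of poly-A spikes, so age and preparation cannot be told apart.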

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

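The tests of carried-over cells, scaling, RNA degradation and preparation, and the splits of the E16.5 arrays, were chosen after the results were seen.

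The Klf4CN effect differed between the ages for 644 genes by a test of the difference itself. Among named genes the log2 differences, PN56 minus E16.5, were 2.03 for Gje1, 3.88 for Alox12, 2.51 for Cdk2ap2, -2.63 for Eva1a, 1.33 for Gpx1, -1.77 for Gprc5b, 1.42 for Ppp1r14b, 3.46 for Lypd6b, 3.09 for Cabp5, 3.91 for Pdlim2, -1.31 for Acta2, 1.95 for Idi1, 1.36 for Cdkn1a and 4.34 for Pmaip1. The value of Pmaip1, whose PN56 WT signal lay below the offset, ran from 2.87 to 6.40 over the alternatives. Among lists the adjusted p of the difference was 0.044 for autophagy and lysosome, 0.044 for cell cycle exit and p53, 0.0234 for crystallins, 5.604e-04 for pigment cells, 0.021 for retinal progenitors and neurons and 3.407e-08 for sterol synthesis, by camera with the preset correlation. With an estimated correlation the adjusted p of these 6 lists lay between 0.407 and 0.891.

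Cdkn1a was called higher in lenses labelled Klf4CN at both ages, while the cell cycle exit and p53 list had a median of 0.12 at E16.5, with 12 of 19 members on the higher side and 1 called (0.05 without E16.5 Klf4CN replicate 3), and of 0.43 at PN56 (0.24 without PN56 Klf4CN replicate 2), with an adjusted p = 0.236 and 0.254 at an estimated correlation. Carried-over pigment and retinal cells would raise their own markers at least as much as a gene they bring along, and at PN56 the highest median of their lists was 0.37, that of photoreceptors (-0.31 and 1.15 without PN56 Klf4CN replicates 1 and 2), against 3.05 for Cdkn1a (2.95 at the lowest with 1 array left out), which argues against them for Cdkn1a at PN56 but not for the list. At E16.5 the median of retinal progenitors and neurons was 1.65 (0.63 and 2.02 without E16.5 WT replicates 1 and 2) against 1.69 ± 0.20 (SE) for Cdkn1a. With the mean of the pigment and retinal markers as a covariate the medians of these lists went to 0.50 and -0.22. That fall follows from building the covariate on their members and supports nothing by itself. With the covariate Cdkn1a was at 1.90 ± 0.27 (SE), with 95% intervals from 1.32 upward, and from 0.91 upward at the lowest with 1 E16.5 array left out. With all arrays the change of Cdkn1a thus did not shrink with the covariate, but its call ended (limma adjusted p = 0.176, and from 0.069 to 0.507 with 1 E16.5 array left out). The error widened and the residual degrees of freedom went from 6 to 5. These intervals are unadjusted, and Cdkn1a was the only gene called on these same arrays, so they do not decide on carry-over at E16.5. The rule used for PN56 does not go against it either, the retinal median lying near the change of Cdkn1a. Scaling between arrays is argued against at PN56, where the highest limma adjusted p of Cdkn1a under quantile normalization and centring on the median was 2.05e-05. Loss of Klf4, whose signal was not lower on probe sets that may lie outside the deleted part, stays open and untested. So does a Cre transgene that the labels do not give for WT animals. Carried-over cells at E16.5, a part played by them at PN56, a change within them and other differences between the pools stay open too.

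Of the carried-over cell markers, 9 pigment and 13 retinal genes were measured, 0 of either stood in another list, and 8 and 13 had a mean signal of at least 45 in E16.5 WT. Pmel, a pigment marker, had 592 ± 373 in WT and 2252 ± 1108 in lenses labelled Klf4CN at E16.5 (SD, n = 3 each). Dct, another, had 266 ± 187 and 1310 ± 906, and at PN56 mean signals of 3722 and 1354. Atoh7, a retinal marker named after its values were seen, had 1779 ± 1982 and 3189 ± 2259 at E16.5.

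For the count of genes called at E16.5, the real split of the 6 arrays gave 1 gene and the highest other split 11, with 2 of the 10 splits giving as many as the real one. The number of splits is too small for a share under 0.05. The split with 11 exchanged WT replicate 3 and Klf4CN replicate 1. The other 8 splits called 0. The count of 11, several times the real one, may point to a structure of the samples, which was not tested.

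The control probe set for the 5' part of 18S ribosomal RNA, which enters no comparison, had a mean signal of 21780 on E16.5 arrays labelled Klf4CN against 1869 on WT arrays, and of 8353 against 1699 at PN56, the groups not overlapping at either age. The probe sets for its middle and 3' parts were at 2950 against 1209 and 1106 against 516 at E16.5, without overlap, but at 1962 against 2216 and 2943 against 2257 at PN56, where the groups overlapped. At E16.5 neither 3' to 5' ratio differed between the genotypes beyond the spread. The Actb ratio differed by -0.104 (1.353 ± 0.021 on arrays labelled Klf4CN and 1.457 ± 0.111 on WT arrays, SD, n = 3 each). The Gapdh ratio was 0.838 ± 0.012 and 0.833 ± 0.026. The test counted only opposite shifts of both ratios, each beyond the spread, against RNA degradation, so ratios this alike leave degradation undecided. A difference in the preparation of labelled RNA cannot be told apart from genotype, because 0 of the 10 samples have a batch, lot or date in their labels. An effect of genotype stays open and untested.

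The control probe set for the B1 repeat stood out on PN56 Klf4CN replicate 2, with a signal of 47064 against 4987 on replicate 1 of that group and 3652 and 986 on the PN56 WT arrays. At E16.5 it lay between 34448 and 36408 on WT arrays and between 30318 and 32598 on arrays labelled Klf4CN, without overlap. The control signal for the 5' part of Gapdh did not overlap either, at 35690 ± 1717 and 31850 ± 1310 (SD, n = 3 each). Nor did that for its 3' part, at 29760 ± 2345 and 26660 ± 772, or the cre hybridisation spike, at 43390 ± 4626 and 38580 ± 1276. The ribosomal RNA controls were higher on arrays labelled Klf4CN, also without overlap. The Actb controls and the poly-A spikes dap, lys, phe and thr overlapped. Chance gives no overlap for 10% of signals, a smaller share than among these controls. The cause of the lower signals was not tested.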

How the results depend on the processing

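The carry-over covariate at E16.5, also with an array left out for Cdkn1a, and the unadjusted threshold for shared genes were chosen after the data were seen, and the other alternatives before. Across named genes, followed in neither the filters, every probe set by itself, other thresholds nor the fit on 2 groups, 2675 values kept their direction and side of the threshold, 159 lost the call, 22 gained it and 0 changed direction in the alternatives run. Of 157 values of named genes 74 had another probe set above the filter, and for 9 of them at least 1 such probe set had the opposite sign. For gene lists, 803 kept both, 89 lost the call, 32 gained it and 14 changed direction. The cause was not tested for any change below, except that stricter or looser thresholds and testing every probe set change counts by construction. Quantile normalization, which gives all arrays the same distribution, also takes out joint changes of the brightest signals by construction. The carry-over covariate likewise lowers the medians of the pigment and retinal lists, from which it was built. Signal over background limits dim genes, whose fold changes shrink with a larger offset.

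At E16.5, where 1 gene was called, the count was 3 with quantile normalization, 8 with array weights, 7 at adjusted p under 0.10, and 0 with the mean of a gene's probe sets, with no intensity trend, with a fit on the 2 compared groups and with the carry-over covariate. It ran from 0 to 3 over arrays left out. At PN56 (1750) it was 2701 for every probe set by itself, 1034 with the mean of probe sets, 1165 with no trend, 637 with array weights, 2683 at adjusted p under 0.10, 620 at 2-fold or more and 806 with a fit on the 2 groups, and from 1058 to 1905 over arrays left out. The difference between ages (644) had 294 with the mean of probe sets, 201 with no trend, 322 with array weights, 1169 at adjusted p under 0.10, 351 at 2-fold or more, and 277 to 940 over arrays left out. Age in WT (7483) had 13639 for every probe set and 4165 at 2-fold or more, with 6545 to 7756 over arrays left out, and age in Klf4CN (7004) had 12620 and 3745, with 5850 to 7277. Genes shared between the ages (1) were 2 with quantile normalization, 0 with the mean of probe sets, 3 at adjusted p under 0.10, 91 at the unadjusted threshold, and 0 to 2 over arrays left out. Klf4 at PN56 was at 1.0407 by the other probe set (limma adjusted p = 0.077), and between 1.68 and 2.09 over arrays left out; at E16.5 it lay between 0.25 and 0.85.

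Lists past the test at E16.5 (14) were 0 with an estimated correlation and 0 by fry, and 10 to 15 over arrays left out. At PN56 (5) they were 2 with quantile normalization, 9 with offset 64, 9 with no filter, 3 with the mean of probe sets, 0 with an estimated correlation, and 5 to 10 over arrays left out. With age in WT (8) they were 0 with an estimated correlation and 20 by fry, and 8 to 9 over arrays left out. By fry 7 lists passed at PN56, among them all 5 past camera. With the carry-over covariate the medians of hypoxia response and of retinal progenitors and neurons at E16.5 changed sign, to 0.0203 and -0.2155. At PN56 lists not past the test changed the direction of camera: Kruppel-like factors with the filter at the 60th percentile (median -0.1687) and without PN56 WT replicate 1 (0.0211) or PN56 Klf4CN replicate 1 (-0.09), in a range of -0.141 to 0.1104 over arrays left out, hypoxia response with every probe set (-0.0832), cell cycle with the mean of probe sets (-0.0411), Notch signalling without PN56 WT replicate 1 (-0.2497) or PN56 Klf4CN replicate 2 (-0.1442), in a range of -0.2497 to 0.0762, photoreceptors without PN56 Klf4CN replicate 1 (-0.3084), in a range of -0.3084 to 1.1489, epithelial-mesenchymal transition with every probe set (-0.0912), with the mean of probe sets (-0.1039) and without PN56 Klf4CN replicate 2 (0.0521), in a range of -0.2681 to 0.0521, and lens transcription factors without PN56 Klf4CN replicate 2 (0.0061), in a range of -0.2991 to 0.0061.

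With the replicate number as a block, 6 genes were called at E16.5, 2150 at PN56, 952 for the difference, 7136 and 6688 with age, and 2 were shared; 15, 8 and 8 lists passed at E16.5, at PN56 and with age in WT. Arrays of the same number deviated together by 0.2678, 0.2414 and 0.0508 at E16.5 and by 0.0422 at PN56. Arrays of different number did so by -0.2789 to 0.0626 at E16.5, the highest being WT replicate 3 with Klf4CN replicate 2, and by -0.0422 at PN56. Deviations from a group mean cancel out, so with 2 arrays per group the PN56 values differ in sign only, by construction. At E16.5 this also ties the values for different numbers to those for the same number. These values do not settle whether the numbers pair the samples. The main fit has no block because the numbers are not stated to mark a shared litter, batch or day.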

Other observations

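Genes of growth factor signalling and of the hypoxia response changed in both directions at PN56. Of 16 genes of FGF signalling 3 rose and 2 fell, the list not past the test (camera adjusted p = 0.208): Dusp4, a MAP kinase phosphatase, rose by 2.08, Etv5 by 0.87 and Spred1 by 0.78, and Fgfr2, an FGF receptor, fell, at -0.79. A second probe set of Spred1 had the opposite sign, and its call was lost without any 1 of the PN56 arrays. Of 15 hypoxia response genes 4 rose and 3 fell (camera adjusted p = 0.551), with Ankrd37 at 1.47, Egln3 at 1.39, Vegfa at 1.26 and Hif1a at -0.62, a second probe set of Egln3 having the opposite sign. Of 19 interferon response genes 2 rose, B2m by 1.53 and Rsad2, from a WT signal of 11.5, below the offset, by 1.61 (camera adjusted p = 0.078), and of 15 Notch signalling genes 2 rose, Hey1 by 0.84 and Jag1 by 0.63 (camera adjusted p = 0.813). Both other probe sets of Rsad2 had the opposite sign. Its call was lost without PN56 WT replicate 1 or PN56 Klf4CN replicate 1, and that of Hey1 without either PN56 WT array or PN56 Klf4CN replicate 2. The calls lost with a gene's probe sets averaged included those of Fgfr2, Egln3, Hif1a, Spred1 and Rsad2, those lost with array weights Egln3, Hey1, Rsad2 and Spred1, and those lost with no intensity trend Hey1, Rsad2 and Spred1; that of Rsad2 was also lost with an offset of 64. The interferon response list was past the test with an offset of 64 (camera adjusted p = 0.048).

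Of 21 lens transcription factors 1 rose and 2 fell at PN56 (camera adjusted p = 0.456), Mafg rising by 0.81, and Sox2 was at -0.41, not past the test (limma adjusted p = 0.058). Of 15 Kruppel-like factors 1 rose, Klf4 itself, and 0 fell (median -0.14, from -0.14 to 0.11 over arrays left out, with a mean of 0.12; camera adjusted p = 0.880). Klf5 was at 1.16 (limma adjusted p = 0.072) and Klf16 at -0.66 (0.062), neither past the test. Sox2 was past it with quantile normalization (0.043) and with the replicate number as a block (0.029). Klf5 was past it with quantile normalization (0.017), centring on the median (0.045), an offset of 64 (0.049) and the replicate number as a block (0.042). Klf16 was past it without E16.5 Klf4CN replicate 2 (0.044) and, at -0.87, without PN56 Klf4CN replicate 1 (0.038). At E16.5 the medians were -0.06 for lens transcription factors and 0.13 for Kruppel-like factors, with 0 called by limma in either (camera adjusted p = 0.595 and 0.3196).

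A hypothesis is that values of adult lenses labelled Klf4CN were displaced toward embryonic values, since 990 of the 1294 genes called both in that comparison and with age in WT (76.5%) had opposite directions. Of these, 531 were higher in lenses labelled Klf4CN and lower with age, against 249.1 for independent lists, and 459 the reverse, against 234.1, and part of the excess may come from the PN56 WT arrays, which enter both comparisons and cannot be split with 2 in each part. Over all genes the covariance of the log2 fold changes was -0.267, within the range of 100 simulations with no effect (mean -0.077, from -0.297 to 0.052), so the shared arrays may account for it there. Among the 3363 brightest genes the covariance was -0.172, below the lowest simulation at -0.075 (mean -0.016). For those genes this argues against random error of the shared arrays, which the simulations include, and against dim signals as the whole source. The simulations hold no steady difference in array scale between the genotypes, so they cannot decide on one. The cre hybridisation spike had the same pattern, at 43390 on E16.5 WT, 110200 on PN56 WT and 73060 on PN56 Klf4CN arrays. So had the Actb 3' control, at 36840, 81660 and 62490. Displacement of the brightest genes thus stays open. Both covariances were set out as tests before their results were seen, and reading the second against the shared arrays was added after. Pearson's r across genes was -0.349 over all genes and -0.342 over the brightest, within the simulated ranges (-0.945 to 0.899 and -0.956 to 0.898, with means of -0.504 and -0.505), which are too wide to tell.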
